A study of Homo sapiens with 9 samples.

How the data were processed

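RNA sequencing measured gene expression in 9 libraries of total RNA from KP-4, a human cell line derived from a pancreatic adenocarcinoma. The cells had been reverse-transfected for 72 h with 20 nM of a control siRNA, of BRD4 siRNA #1 or of BRD4 siRNA #2. Each group had 3 libraries, numbered by experiment. The labels call the replicates independent preparations and do not say whether these were separate cultures, so p-values measure the spread between these preparations. The libraries were made with a TruSeq RNA v2 kit, which does not mark the strand of origin.

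The authors demultiplexed reads with bcl2fastq 2.15.0.4, aligned them to GRCh37 with TopHat2 2.0.10 and counted reads per gene with HTSeq 0.5.4p3, per the labels. The labels also name DESeq2 1.6.3 for their own comparison, whose output was not used here. The annotation release, the strand setting and the filters of the counting are not given in the sources used here. The deposited values are counts, whole reads per Ensembl gene, not normalized. Each of the 9 files held 63677 genes and 0 lines that named no gene, and 36040 genes had at least 1 read in some library. Symbols and positions came from GENCODE release 44 lifted to GRCh37, which may differ from the annotation the authors counted with. They matched 55665 gene IDs, which held 99.293% of the counts, and 8012 IDs had no match.

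Library totals lay between 32879415 and 36427254 counts. Genes were tested when they passed the filterByExpr filter of edgeR with a count minimum of 10, which left 18874 genes. Counts were scaled by the trimmed mean of M values. edgeR 4.0.16 (R 4.3.3, limma 3.58.1) fitted all 9 libraries as 3 groups with 6 residual degrees of freedom, and a two-sided quasi-likelihood F test compared each siRNA with control, the mean of both siRNAs with control, and siRNA #2 with siRNA #1. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, and a gene was called changed at an adjusted p under 0.05. The common biological coefficient of variation was 12.5%. Standard errors (SE) of log2 fold changes were the absolute log2 fold change divided by the square root of F. Levels are CPM, counts relative to the scaled library total as edgeR gives them, shown as mean ± SD over the 3 libraries of a group. Fold values are edgeR's fitted changes. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 did the sequence searches and the plots.

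A set of 24 gene lists, the comparisons, the tests and the rule for naming genes were fixed before the data were examined. The lists held 668 members, of which 590 were tested and 3 (UHRF1, SOD2 and PECAM1) matched no ID in the files. camera, from limma, compared each list with the other genes tested at a preset correlation of 0.01 between genes, adjusted over the lists within a comparison. The same test was rerun with a correlation estimated from the data, and fry tested each list without reference to other genes. Members called were counted after adjustment over all genes and after adjustment over the list alone. A list with fewer than 5 tested members got counts only. The genes always named were BRD4, BRD2, BRD3, BRDT and a central gene of several lists. The rule added the 10 largest rises and the 10 largest falls shared by both siRNAs, up to 4 members per list called the same way under both siRNAs, and the 5 genes highest and 5 lowest under siRNA #2 relative to siRNA #1. The ranked genes needed a mean of 2 CPM in some group.

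Replicates were compared by a chi-square test of their counts. No pair of a group came within sampling noise, since chi-square per degree of freedom was 5.53 or more in every pair. Experiment numbers were shared by the 3 groups, so the labels pair the libraries. Deviations from group means correlated at -0.051 to 0.244 between the 9 library pairs with the same number, 5 of them over 0.1, and at -0.251 to 0.201 between libraries with different numbers. Between the siRNA groups, pairs with the same number gave 0.116, 0.212 and 0.18, and pairs with different numbers -0.163 to -0.022. Control replicate 3 gave 0.147 and 0.244 with the siRNA libraries of its number, and control replicates 1 and 2 gave -0.051 to 0.055 with theirs. A fit with experiment as a block was an alternative.

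Both siRNAs were compared with the same 3 control libraries, which alone gives their fold changes a positive correlation. The overlap was therefore set beside 20 simulated runs of unchanged groups against shared controls and beside the overlap of independent lists of the same sizes. In these runs all 9 libraries, controls included, were drawn anew from the control means, with the same dispersion of a gene in every group. The test was also tried on simulated data, with 50 genes changed by a known fold among 17960. It called 36% of genes changed 1.5-fold and 88% of those changed 2-fold in a simulated siRNA #1, with 6 unchanged genes called. In siRNA #2 these shares were 38% and 96%, with 7 unchanged genes called. A list changed 1.4-fold was called in 3 of 3 comparisons, with 4 calls in 66 tests of other lists. Genes were drawn independently there, so these calls do not show how lists of correlated genes behave. In the siRNA #1 comparison, the correlation estimated from the data ran from -0.035 for autophagosome-lysosome fusion to 0.328 for S phase and DNA replication.

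The alternatives were median-of-ratios factors, library totals alone, DESeq2 1.42.0, limma-voom, no filter, a mean of at least 5 CPM, the experiment block, a test against a 1.2-fold change (glmTreat), fits of only the groups compared, and leaving out each library in turn. Counts of list members and of 2-fold changes without control replicate 1 were added after that library was seen to stand apart. Other splits of the libraries were refitted for each count of genes. For the difference between siRNAs, 7-base words in 3' untranslated regions (UTRs) of 50 to 10000 bases were scored in 11118 genes with a mean of at least 2 CPM in some group, BRD4 left out, with 1000 permutations.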

Results

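The data were counts of RNA sequencing reads per gene in KP-4 cells, a human pancreatic adenocarcinoma line, 72 h after transfection with control siRNA or with either of 2 siRNAs against BRD4 (n = 3 libraries per group). BRD4 is a bromodomain protein that binds acetylated histones. The series asked whether BRD4 represses the transcription of autophagy and lysosome genes. Control libraries held 36078240 to 36427254 counts, siRNA #1 libraries 35250848 to 35365172 and siRNA #2 libraries 32879415 to 33574158. Counts on the mitochondrial genome made up 1.97% to 2.11% of the control libraries, 2.61% to 3.00% of the siRNA #1 libraries and 2.60% to 2.82% of the siRNA #2 libraries.

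The first 3 principal components of log2 CPM held 51.6%, 23.9% and 10.9% of the variance. The first component separated controls from both siRNAs and the second separated the siRNAs from each other. On the third, control replicate 1 lay at -44.1 against 27.0 and 28.3 for control replicates 2 and 3. Over 14366 genes, 555 differed more than 2-fold between control replicate 1 and the mean of the other controls, against 21 between control replicates 2 and 3. The median SD of log2 CPM within a group was 0.221 in controls, 0.074 under siRNA #1 and 0.095 under siRNA #2.

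**Figure D1:**
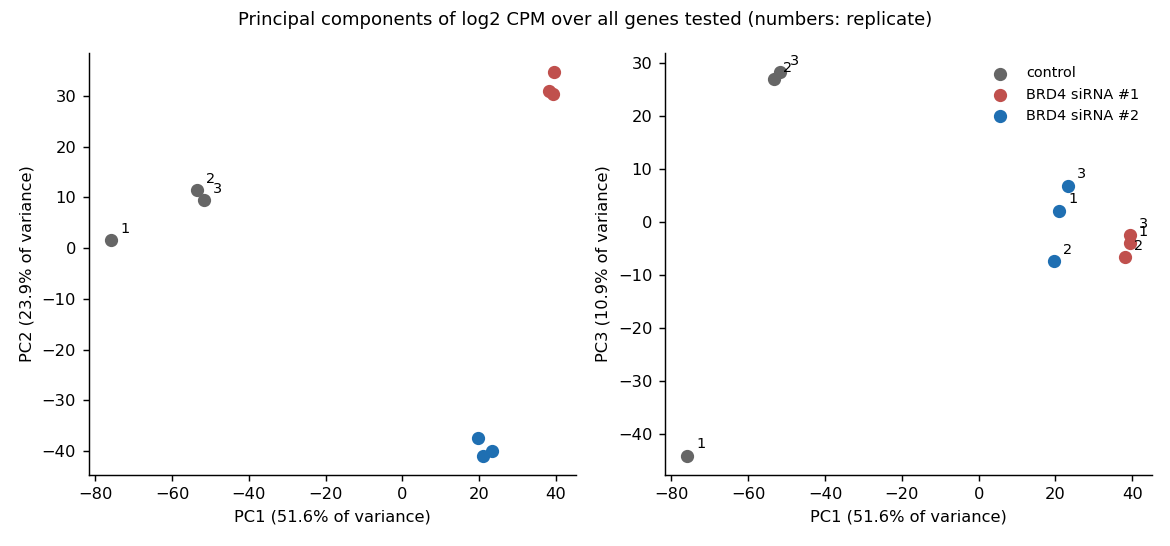
Principal components of log2 CPM, with 1 point per library colored by group (component 1 on the x axis, component 2 or 3 on the y axis, percent of variance on each axis). Control replicate 1 lies at -44.1 on component 3, apart from control replicates 2 and 3 at 27.0 and 28.3.

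Both siRNAs lowered BRD4 itself, which checks the labels. BRD4 (ENSG00000141867, GRCh37 chromosome 19, 15346330 to 15443356, minus strand) fell from 130.7 ± 20.8 CPM in controls to 18.1 ± 1.87 CPM under siRNA #1 and 14.8 ± 0.219 CPM under siRNA #2 (SD, n = 3). These were falls of 7.23-fold (log2 fold change -2.85, SE 0.129, adjusted p = 1.8e-07) and 8.82-fold (-3.14, SE 0.131, adjusted p = 1.9e-07). The levels under both siRNAs differed by -0.29 on the log2 scale (adjusted p = 0.12). BRD3, a paralog, stood at 40.7 ± 10.2 CPM in controls, 32.0 ± 3.47 under siRNA #1 and 32.5 ± 1.33 under siRNA #2 (adjusted p = 0.097 and 0.12). BRD2, another paralog, stood at 1.6, 1.46 and 1.19 CPM (adjusted p = 0.62 and 0.11). BRD2 lies in the major histocompatibility region, where the 11 protein-coding genes tested had a median of 1.22 CPM in controls, against 28.22 CPM for 568 genes elsewhere on chromosome 6, so the counts of BRD2 may not reflect its expression. BRDT, the testis paralog, had 0 counts. Without control replicate 1, BRD3 fell by 0.52 (adjusted p = 0.0012) and 0.50 (adjusted p = 0.0017) on the log2 scale, and without control replicate 2 BRD2 fell by 0.57 under siRNA #2 (adjusted p = 0.038).

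Of the 15 tested members of the BET family and P-TEFb list, 3 rose and 4 fell under siRNA #1, and 3 rose and 6 fell under siRNA #2. Adjusted over the list alone, 2 rose and 4 fell, and 3 rose and 6 fell. HEXIM1, which holds the elongation kinase P-TEFb inactive, fell 1.86-fold and 2.20-fold under siRNA #1 and siRNA #2. MEPCE, a partner in the same inhibitory complex, fell 1.71-fold and 1.66-fold, and CDK9, the P-TEFb kinase, rose 1.56-fold and 1.54-fold. The list as a whole did not differ from other genes (adjusted p = 0.538 and 0.115), with a median of 0.19 and a mean of -0.10 under siRNA #1, where camera's direction was down. In control replicate 1 the list had a median 0.26 log2 below the other controls, and without that library the siRNA #2 test gave adjusted p = 0.0118, with 6 members higher and 5 lower under siRNA #1 and 5 and 8 under siRNA #2.

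Many genes changed under each siRNA, mostly by less than 2-fold. With siRNA #1, 4480 genes rose and 4610 fell, of 18874 tested, and 1675 rose and 950 fell at least 2-fold. With siRNA #2, 4242 rose and 4076 fell, and 1452 rose and 741 fell at least 2-fold. For the mean of both siRNAs, 4695 genes rose and 4833 fell, of which 1447 and 645 changed at least 2-fold. The balance of rises and falls depended on the setting, scaling included, and with library totals 4845 rose and 4164 fell under siRNA #1, 4545 and 3795 under siRNA #2, and 5065 and 4393 for the mean. Without control replicate 1, the counts at least 2-fold higher and lower were 1709 and 884 for siRNA #1, 1521 and 752 for siRNA #2, and 1477 and 616 for the mean.

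The siRNAs shared 5522 changed genes with the same direction, 2790 higher and 2732 lower, and 310 genes were called in opposite directions. Independent lists of the same sizes would share 1007 higher and 996 lower genes. Simulated unchanged groups shared 0.05 genes on average and 1 at most, with the shared controls simulated too. The deviation of control replicate 1 was thus absent from these runs, and the overlap that the real controls alone would give is not known. Across genes, which are not independent replicates, the log2 fold changes of both siRNAs correlated at r = 0.728, against a mean of 0.496 in the simulations. Their covariance was 0.435, which is 0.411 above the simulated 0.024. The same sign was seen in 77.3% of genes, against 66.5% in the simulations. The simulations gave all groups the same spread per gene, while the median SD of log2 CPM was 0.221 in controls and 0.074 and 0.095 under the siRNAs. Noisier shared controls alone raise the correlation and the share with the same sign. Neither of these comparisons therefore shows shared effects by itself.

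**Figure D2:**
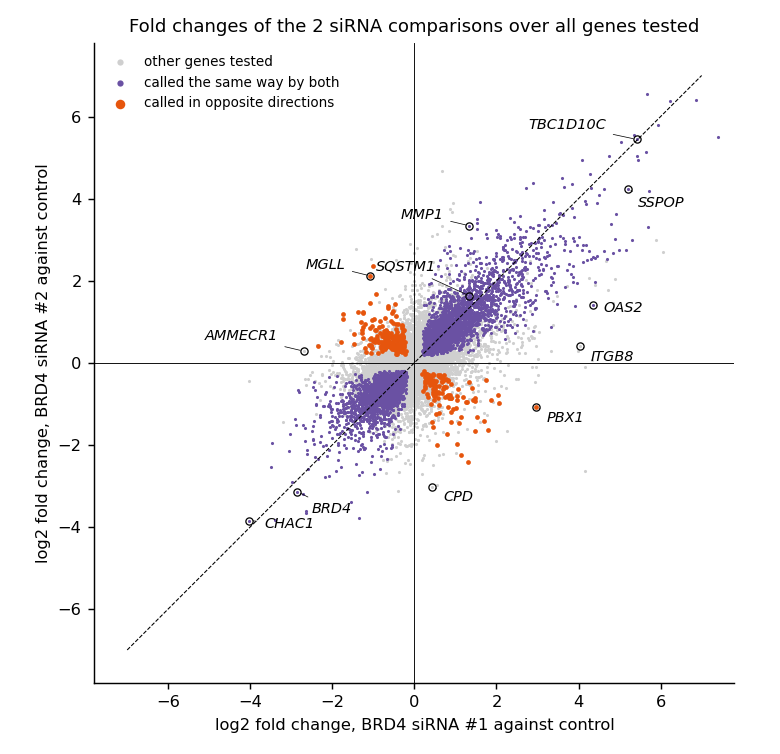
Log2 fold change against control under siRNA #1 (x axis) and siRNA #2 (y axis), 1 point per tested gene, with the dashed line marking equal change. Purple points are the 5522 genes called in the same direction by both siRNAs, and orange points are the 310 called in opposite directions.

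More lysosomal hydrolases rose than fell under each siRNA. Of 52 tested, the enzymes that break down material in the lysosome, 33 rose and 6 fell under siRNA #1, and 30 rose and 5 fell under siRNA #2. Their median log2 fold changes were 0.57 and 0.56, and 26 members rose under both. IDUA, which degrades glycosaminoglycans, rose from 4.88 ± 0.0890 CPM to 18.9 ± 1.32 and 17.1 ± 1.31 CPM. SIAE, a sialic acid esterase, rose 3.68-fold and 2.92-fold, and cathepsin S (CTSS) rose 3.34-fold and 5.93-fold. Cathepsin B (CTSB), at 254 ± 12.7 CPM in controls, rose 1.65-fold and 1.59-fold. Cathepsin V (CTSV) went the other way, falling 3.60-fold and 2.45-fold. Cathepsin D (CTSD) rose 1.38-fold under siRNA #2 (adjusted p = 0.0076) and had a log2 fold change of 0.23 under siRNA #1 (adjusted p = 0.13), or 0.38 without control replicate 1 (adjusted p = 1.7e-04). Reads of SIAE and CTSD are less certain, since 34.8% of SIAE exon bases overlap TBRG1 and 23.4% of CTSD exon bases overlap PRADX on the other strand.

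Proteins of the lysosomal membrane and its transport followed, with 21 of 36 tested members higher and 3 lower under siRNA #1, and 25 higher and 0 lower under siRNA #2 (medians 0.41 and 0.55). HGSNAT, an acetyltransferase of the lysosomal membrane, rose 2.80-fold and 2.21-fold. SLC17A5, the sialic acid exporter, rose 3.16-fold and 1.78-fold, and NPC1, the cholesterol exporter, rose 1.96-fold and 1.79-fold. GNPTG, a subunit of the enzyme that tags hydrolases for the lysosome, rose 2.20-fold and 1.63-fold, although 44.3% of its exon bases overlap UNKL. LAMP2, a main protein of the lysosomal membrane, rose from 210 ± 20.7 CPM to 324 ± 8.18 and 296 ± 13.8 CPM. LAMP1 rose 1.57-fold and 1.18-fold. The siRNA #2 call of LAMP1 was lost without control replicate 2 (adjusted p = 0.065), control replicate 3 (adjusted p = 0.07) or siRNA #2 replicate 3 (adjusted p = 0.054).

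The tests of these lists against other genes gave adjusted p = 2.85e-09 and 2.03e-09 for hydrolases, but adjusted p = 0.24 and 0.185 with an estimated correlation. For the membrane list they gave adjusted p = 2.57e-04 and 6.06e-08. With an estimated correlation these became adjusted p = 0.0786 for siRNA #1, and adjusted p = 0.0133 for siRNA #2, where the call held. With p-values adjusted over the list alone, 36 hydrolases rose and 7 fell under siRNA #1, and 30 rose and 5 fell under siRNA #2. For the membrane list, adjusted over the list alone, 21 rose and 4 fell, and 26 rose and 1 fell. In control replicate 1 the hydrolases had a median 0.21 log2 above the other controls, and the membrane list -0.03. Without that library, 38 hydrolases rose and 7 fell under siRNA #1, and 34 rose and 5 fell under siRNA #2. The membrane list then had 25 members higher and 4 lower, and 27 higher and 1 lower.

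Of 21 tested subunits of the vacuolar ATPase, the proton pump that acidifies lysosomes, 9 rose and 1 fell under siRNA #1, and 10 rose and 1 fell under siRNA #2. In counts adjusted over the list alone, 10 rose and 1 fell under each. ATP6AP1 rose 1.59-fold and 1.31-fold, ATP6V1A 1.24-fold and 1.51-fold, and ATP6V0D1 1.23-fold and 1.56-fold. ATP6V1C2, a low isoform at 1.92 CPM in controls, fell 1.58-fold and 1.54-fold, with 29.5% of its exon bases shared with PDIA6. The list test missed its threshold (adjusted p = 0.373 and 0.0529, or 0.721 and 0.396 with an estimated correlation). In control replicate 1 these subunits had a median 0.35 log2 above the other controls. Without that library the list passed at the preset correlation, with adjusted p = 0.0191 and 1.92e-04, and 11 rose and 0 fell under siRNA #1, and 15 rose and 1 fell under siRNA #2. Without siRNA #2 replicate 1 it gave adjusted p = 0.0458 for siRNA #2. The siRNA #1 calls of ATP6V1A and ATP6V0D1 and both calls of ATP6V1C2 were lost in several fits that left out a library. They reached adjusted p = 0.06 for ATP6V1A without siRNA #1 replicate 1 and 0.059 without replicate 2, and 0.13 for ATP6V0D1 without control replicate 3. For ATP6V1C2 they reached adjusted p = 0.11 without siRNA #1 replicate 3, and 0.12 in the siRNA #2 comparison without siRNA #2 replicate 1.

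Genes for the fusion of autophagosomes with lysosomes also rose more often than they fell, with 15 of 21 tested members higher and 2 lower under siRNA #1, and 13 higher and 1 lower under siRNA #2. TECPR1, which tethers the membranes, rose from 36.6 ± 0.958 CPM to 72.2 ± 1.24 and 71.8 ± 1.67 CPM. TECPR2 rose 1.97-fold and 1.88-fold, EPG5, another tether, 1.95-fold under each, and PLEKHM1, an adaptor of late endosomes, 1.28-fold and 2.77-fold. The siRNA #1 call of PLEKHM1 was lost without control replicate 2 (adjusted p = 0.052) or siRNA #1 replicate 1 (adjusted p = 0.058). The list medians were 0.36 and 0.45, and 12 members rose under both siRNAs. Against other genes the list gave adjusted p = 0.0065 and 2.16e-04. With an estimated correlation it gave adjusted p = 0.125 for siRNA #1 and kept its call for siRNA #2 (adjusted p = 0.042). Adjusted over the list alone, 16 rose and 2 fell, and 14 rose and 1 fell. The median in control replicate 1 was 0.03 above the other controls, and without it 17 rose and 2 fell, and 16 rose and 1 fell.

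Among genes that build autophagosomes, more rose than fell under siRNA #2. Of 41 tested, 17 rose and 2 fell under that siRNA, and 13 rose and 11 fell under siRNA #1. MAP1LC3B, which encodes the autophagosome marker LC3B, rose from 125 ± 18.3 CPM to 181 ± 6.32 and 185 ± 4.21 CPM. BECN1, a subunit of the lipid kinase that starts autophagosomes, rose 1.30-fold and 1.55-fold. ATG2A, a lipid transfer protein, rose 1.69-fold and 1.74-fold, ATG16L2 1.61-fold and 1.76-fold, and VMP1 1.55-fold and 1.39-fold. WIPI1 rose 1.27-fold and 3.76-fold, with 24.4% of its exon bases shared with ARSG. The siRNA #1 call of WIPI1 was lost without siRNA #1 replicate 1 (adjusted p = 0.063) or replicate 3 (adjusted p = 0.09).

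The autophagosome formation list had median log2 fold changes of 0.12 and 0.17, and gave adjusted p = 0.79 for siRNA #1 and 0.00543 for siRNA #2, or adjusted p = 0.185 with an estimated correlation. The difference between the siRNAs was itself past the test (11 members higher and 2 lower under siRNA #2, adjusted p = 0.00836), but not with limma-voom (adjusted p = 0.0542) or with an estimated correlation (adjusted p = 0.45). With p-values adjusted over the list alone, 14 rose and 11 fell under siRNA #1, and 17 rose and 2 fell under siRNA #2. The list stood 0.11 log2 higher in control replicate 1 in median, and without that library 17 rose and 11 fell, and 23 rose and 3 fell. In the comparison of the siRNAs, 15 members were then higher and 6 lower under siRNA #2.

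SQSTM1 (ENSG00000161011, chromosome 5, 179233398 to 179265078, plus strand), which encodes the autophagy receptor p62, rose from 1046 ± 139 CPM to 2648 ± 165 CPM under siRNA #1 and 3236 ± 137 CPM under siRNA #2. These were rises of 2.53-fold (log2 1.34, SE 0.096, adjusted p = 3.0e-06) and 3.10-fold (log2 1.63, SE 0.096, adjusted p = 1.3e-06). MRNIP on the other strand shares 21.0% of SQSTM1 exon bases. Of 19 tested selective autophagy receptors, 7 rose and 4 fell under siRNA #1, and 6 rose and 3 fell under siRNA #2. OPTN rose 1.84-fold and 1.68-fold and TOLLIP 1.41-fold and 1.80-fold, while TEX264, a receptor for the endoplasmic reticulum, fell 1.89-fold and 1.41-fold. TEX264 lost its siRNA #2 call without siRNA #2 replicate 3 (adjusted p = 0.056). The receptor list did not differ from other genes (medians 0.10 and 0.18, adjusted p = 0.34 and 0.115). In counts adjusted over the list alone, 8 rose and 5 fell, and 6 rose and 3 fell. The median of control replicate 1 was 0.07 above the other controls, and without it 8 rose and 4 fell, and 7 rose and 3 fell, with adjusted p = 0.0496 for siRNA #2.

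Among regulators of TFEB and mTORC1, which control lysosome genes, 10 of 33 tested rose and 6 fell under siRNA #1, and 10 rose and 4 fell under siRNA #2, the same counts as adjusted over the list alone. TFE3, a transcription factor for lysosome genes, rose 1.57-fold and 1.68-fold. TFEB, its paralog, had log2 fold changes of 0.11 and -0.42 (adjusted p = 0.74 and 0.21), and without control replicate 3 it fell by 0.67 under siRNA #2 (adjusted p = 0.028). SESN3 rose 3.60-fold and 3.75-fold, FNIP1 2.01-fold and 1.66-fold, and SESN2 fell 2.19-fold and 1.57-fold. The siRNA #2 call of FNIP1 was lost without siRNA #2 replicate 1 (adjusted p = 0.07) or replicate 3 (adjusted p = 0.06). The list did not differ from other genes (medians 0.04 and 0.08, adjusted p = 0.651 and 0.353). Control replicate 1 stood 0.08 above the other controls in median, and without it 13 rose and 8 fell, and 16 rose and 6 fell.

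**Figure D3:**
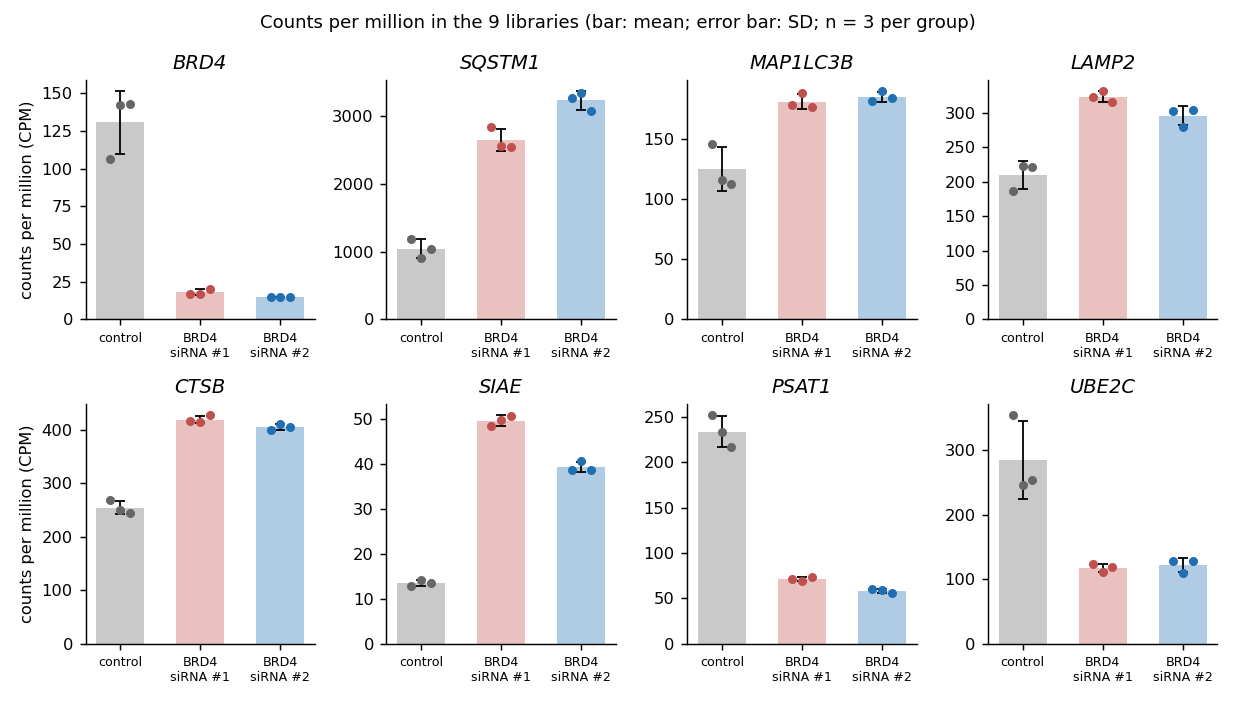
CPM of 8 genes in each library (points), with the group mean (bar, from 0) and SD (error bar), n = 3 per group. BRD4 fell from 130.7 to 18.1 and 14.8 CPM, and SQSTM1 rose from 1046 to 2648 and 3236 CPM.

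Most cell cycle genes tested fell under both siRNAs. Of 34 tested genes of G2 and mitosis, 32 fell under siRNA #1, 31 fell under siRNA #2, 30 fell under both and 0 rose. UBE2C, which drives the degradation of mitotic cyclins, fell from 284 ± 60.1 CPM to 118 ± 6.42 and 122 ± 10.3 CPM. PTTG1, the securin, fell 3.12-fold and 2.12-fold, CCNB2 (cyclin B2) 2.13-fold and 1.92-fold, and MAD2L1, a spindle checkpoint protein, 1.79-fold and 4.10-fold. Of 31 tested S phase and DNA replication genes, 29 fell and 0 rose under siRNA #1, and 27 fell and 1 rose under siRNA #2. MCM3, a subunit of the replicative helicase, fell 1.72-fold and 2.35-fold, FEN1 2.12-fold and 1.5-fold, RFC4 1.57-fold and 1.93-fold, and E2F2 2.68-fold and 1.35-fold. E2F2 lost its siRNA #2 call without siRNA #2 replicate 2 (adjusted p = 0.052).

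The mitosis list had medians of -0.65 and -0.85 and gave adjusted p = 2.89e-11 and 1.16e-20 against other genes. This became adjusted p = 0.134 with an estimated correlation for siRNA #1, and the siRNA #2 call held (adjusted p = 0.042). The S phase list had medians of -0.62 and -0.51 and gave adjusted p = 2.85e-09 and 2.18e-08, or adjusted p = 0.24 and 0.251 with an estimated correlation. Adjusted over the list alone, 33 and 34 mitosis genes fell and 0 rose, and 29 and 28 S phase genes fell with 0 and 1 higher. Control replicate 1 stood above the other controls by a median of 0.05 in the mitosis list and 0.18 in the S phase list. Without that library, 34 mitosis genes fell under each siRNA, and the S phase counts were unaltered.

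MYC itself was at 222 ± 18.0 CPM in controls, 180 ± 27.5 CPM under siRNA #1 and 195 ± 34.4 CPM under siRNA #2, with log2 fold changes of -0.31 (adjusted p = 0.092) and -0.19 (adjusted p = 0.3). With the experiments paired as blocks, the siRNA #1 value was -0.32 (adjusted p = 0.015), and without siRNA #1 replicate 3 it was -0.44 (adjusted p = 0.035). Of 30 tested members of the list of MYC and its ribosome biogenesis targets, 19 fell under siRNA #1, 21 fell under siRNA #2 and 0 rose. FBL, which methylates ribosomal RNA, fell 2.28-fold and 2.59-fold, and TCOF1, a factor for ribosomal RNA transcription, fell from 451 ± 13.1 CPM to 245 ± 2.84 and 246 ± 7.86 CPM. NPM1 fell from 587 ± 81.1 CPM to 259 ± 8.60 and 273 ± 17.9 CPM, although reads of NPM1 are hard to place among its copies, and NOP56 fell 1.75-fold and 1.66-fold. The list had medians of -0.37 and -0.40 and gave adjusted p = 2.21e-05 and 6.60e-07, or adjusted p = 0.351 and 0.251 with an estimated correlation. With p-values adjusted over the list alone, 19 and 23 fell. The median in control replicate 1 was 0.31 above the other controls, and without it 21 and 22 members fell.

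Under siRNA #1, the list of ATF4 and unfolded protein response genes had the lowest median of all lists. Under siRNA #2 it lay behind G2 and mitosis, at -0.52 against -0.85. Of 26 tested genes of the ATF4 and unfolded protein response, 17 fell and 3 rose under siRNA #1, and 15 fell and 2 rose under siRNA #2. CHAC1, which degrades glutathione, fell from 26.1 ± 8.29 CPM to 1.6 ± 0.186 and 1.81 ± 0.169 CPM, or 16.2-fold and 14.4-fold. The serine synthesis enzymes PHGDH and PSAT1 fell 3.61-fold and 5.15-fold, and 3.28-fold and 3.99-fold, and TRIB3 fell 4.82-fold and 3.46-fold. The list had medians of -0.91 and -0.52 and gave adjusted p = 4.62e-11 and 1.70e-08, or adjusted p = 0.0786 and 0.0757 with an estimated correlation. In counts adjusted over the list alone, 18 fell and 3 rose, and 16 fell and 3 rose. Control replicate 1 stood 0.12 above the other controls in median, and without it 18 fell and 4 rose, and 16 fell and 3 rose.

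Glycolysis genes fell more often than they rose, with 13 of 24 tested members lower and 4 higher under siRNA #1, and 9 lower and 5 higher under siRNA #2. HK2, the hexokinase of growing cells, fell 1.91-fold and 1.68-fold, PFKFB4 2.28-fold and 1.54-fold, and ENO1 1.49-fold and 1.58-fold, with reads shared by near-identical copies of ENO1. The glucose transporter SLC2A3 rose 3.07-fold and 2.80-fold. The list passed for siRNA #1 (median -0.31, adjusted p = 0.0393, or adjusted p = 0.481 with an estimated correlation) but not without siRNA #1 replicate 3 (adjusted p = 0.0586), with library totals alone (adjusted p = 0.0501) or at a mean of 5 CPM (adjusted p = 0.156). For siRNA #2 the median was 0.00, the mean -0.05 and adjusted p = 0.696. Adjusted over the list alone, 13 fell and 4 rose, and 9 fell and 6 rose. The median in control replicate 1 was 0.20 above the other controls, and without it 13 fell and 6 rose, and 9 fell and 8 rose.

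Of 25 tested cholesterol synthesis genes, 6 fell and 4 rose under siRNA #1, and 8 fell and 3 rose under siRNA #2, the same counts as adjusted over the list alone. ACAT2 fell 1.59-fold and 1.89-fold, SREBF1, the lipid regulator, 1.43-fold and 1.48-fold, and EBP 1.80-fold and 1.49-fold, while DHCR24 rose 1.44-fold under each. HMGCR, the rate-limiting enzyme, rose 1.49-fold under siRNA #1 (adjusted p = 0.0011) and had a log2 fold change of 0.08 under siRNA #2 (adjusted p = 0.56). The siRNA #2 call of EBP was lost without siRNA #2 replicate 1 (adjusted p = 0.056) or replicate 3 (adjusted p = 0.051). The list did not differ from other genes (medians -0.05 and -0.13, adjusted p = 0.581 and 0.187). Without control replicate 1, 9 fell and 4 rose under siRNA #1, and 10 fell and 5 rose under siRNA #2.

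More interferon response genes rose than fell under siRNA #1, and under siRNA #2 the list did not pass its test. Of 35 tested, 21 rose and 4 fell under siRNA #1, and 11 rose and 8 fell under siRNA #2. OAS2, an antiviral enzyme, rose from 0.225 ± 0.0725 CPM to 4.65 ± 1.38 CPM and 0.600 ± 0.122 CPM. STAT1, the transcription factor of the response, rose 3.17-fold and 1.81-fold, IFI44L 7.24-fold and 2.26-fold, and IFIT2 2.63-fold and 2.00-fold. The siRNA #2 call of OAS2 was lost without control replicate 1 (adjusted p = 0.055) or siRNA #2 replicate 1 (adjusted p = 0.06). The list medians were 0.74 and 0.02, with adjusted p = 2.63e-07 for siRNA #1, or adjusted p = 0.241 with an estimated correlation, and adjusted p = 0.774 for siRNA #2. Tested directly, 22 members were lower and 0 higher under siRNA #2 than under siRNA #1 (median -0.66, adjusted p = 9.96e-11, or adjusted p = 0.45 with an estimated correlation). With p-values adjusted over the list alone, 22 rose and 5 fell under siRNA #1, and 12 rose and 8 fell under siRNA #2. Control replicate 1 stood 0.10 above the other controls in median, and without it 21 rose and 5 fell, and 10 rose and 9 fell.

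Genes of the NF-kB inflammatory response rose more often than they fell under each siRNA, with 11 of 23 tested members higher and 1 lower under siRNA #1, and 14 higher and 2 lower under siRNA #2. LIF, a cytokine, rose from 50.3 ± 5.50 CPM to 124 ± 16.9 and 173 ± 46.6 CPM. CSF1, a macrophage growth factor, rose 2.49-fold and 2.96-fold, and the chemokine CXCL5 1.49-fold and 5.14-fold. PTGS2, the inducible cyclooxygenase, fell 2.76-fold and 2.16-fold. IL6 had too few counts to be tested. The siRNA #1 call of CXCL5 was lost without control replicate 2 (adjusted p = 0.054) or siRNA #1 replicate 1 (adjusted p = 0.075). The list had medians of 0.58 and 0.76 and gave adjusted p = 0.00774 and 5.48e-05, or adjusted p = 0.481 and 0.251 with an estimated correlation. The counts adjusted over the list alone were the same. Control replicate 1 stood at a median of -0.17 relative to the other controls, and without it 12 rose and 2 fell, and 14 rose and 3 fell.

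Mesenchymal and extracellular matrix genes rose more often than they fell, with 13 of 27 tested members higher and 2 lower under siRNA #1, and 12 higher and 1 lower under siRNA #2, the same counts as adjusted over the list alone. The members with the largest shared rises were proteases, a receptor and an actin. MMP14, a membrane-bound matrix protease, rose from 730 ± 54.4 CPM to 1841 ± 37.8 and 2650 ± 242 CPM, and MMP1, a collagenase, rose 2.52-fold and 10.1-fold. ITGA5, a fibronectin receptor subunit, rose 3.24-fold and 3.10-fold. The actin gene ACTA2 rose 3.42-fold and 2.87-fold, although 29.1% of its exon bases overlap ACTA2-AS1. VIM (vimentin) fell 1.43-fold under siRNA #1 (adjusted p = 0.0014) and had a log2 fold change of -0.08 under siRNA #2 (adjusted p = 0.56). The list had medians of 0.29 and 0.34 and gave adjusted p = 0.00127 and 5.03e-07, or adjusted p = 0.24 and 0.0811 with an estimated correlation. Relative to the other controls, the median in control replicate 1 was -0.08, and without it 14 rose and 3 fell, and 12 rose and 5 fell.

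Of 15 tested epithelial and classical pancreatic cancer genes, 8 fell and 1 rose under siRNA #1, and 6 fell and 1 rose under siRNA #2. KRT19, a ductal keratin, fell 2.59-fold and 1.85-fold, and FOXA2, an endodermal transcription factor, fell 1.98-fold and 1.92-fold, whereas the tight junction gene CLDN4 rose 3.57-fold and 2.45-fold. CDH1 (E-cadherin) was low in KP-4, at 1.27 ± 0.377 CPM in controls, and fell 1.75-fold (adjusted p = 0.044) and 4.85-fold. The siRNA #1 call of CDH1 was lost without control replicate 2, siRNA #1 replicate 1 or 2, or siRNA #2 replicate 1 or 2 (adjusted p = 0.17, 0.16, 0.12, 0.058 and 0.066), and with library totals (0.057), DESeq2 (0.082) or only the groups compared (0.081). The list did not differ from other genes (medians -0.68 and -0.11, adjusted p = 0.141 and 0.276), but gave adjusted p = 0.0292 for siRNA #1 without control replicate 3. In counts adjusted over the list alone, 9 fell and 1 rose, and 7 fell and 3 rose. The median in control replicate 1 was 0.37 above the other controls, and without it 8 fell and 1 rose, and 6 fell and 4 rose.

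Cyclin-CDK inhibitors and p53 targets went both ways, with 8 of 28 tested members higher and 9 lower under siRNA #1, and 8 higher and 6 lower under siRNA #2. CDKN1A (p21) rose from 91.1 ± 5.65 CPM to 124 ± 12.4 and 276 ± 5.05 CPM. CDKN1C fell 1.53-fold and 2.69-fold, CDKN2C 2.63-fold and 1.46-fold, and BBC3, a promoter of apoptosis, 2.06-fold and 1.93-fold. The list test gave adjusted p = 0.862 and 0.63, and under siRNA #1 the median was 0.10, the mean 0.00 and camera's direction down. Adjusted over the list alone, 8 rose and 9 fell, and 8 rose and 7 fell. Of 26 tested apoptosis regulators, 6 rose and 8 fell under siRNA #1, and 7 rose and 3 fell under siRNA #2. BIRC3, an inhibitor of apoptosis, rose 2.12-fold and 2.47-fold, CASP8 1.4-fold and 1.43-fold, and CASP9 1.34-fold and 1.49-fold. That list gave adjusted p = 0.79 and 0.418, with a median of 0.03, a mean of -0.05 and a downward direction under siRNA #1. With p-values adjusted over the list alone, 6 rose and 8 fell, and 6 rose and 2 fell.

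Messenger RNAs of the mitochondrial genome rose, with 11 of 13 higher under siRNA #1, 7 higher under siRNA #2 and 0 lower. MT-CYB rose from 1469 ± 58.8 CPM to 2726 ± 209 and 2223 ± 107 CPM, MT-ND1 1.31-fold and 1.51-fold, and MT-ND3 1.35-fold and 1.44-fold. MT-ATP8 rose 1.46-fold and 1.33-fold, with 22.2% of its bases shared with MT-ATP6. The list had medians of 0.39 and 0.30 and gave adjusted p = 0.00774 and 0.0461, or adjusted p = 0.3 and 0.335 with an estimated correlation. The siRNA #2 call was lost without siRNA #1 replicate 3 (adjusted p = 0.0513), siRNA #2 replicate 2 (adjusted p = 0.0684) or siRNA #2 replicate 3 (adjusted p = 0.0506). In counts adjusted over the list alone, 11 and 8 rose. Relative to the other controls, the median in control replicate 1 was -0.05, and without it 11 and 10 rose.

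Markers of other cell types were scarce in these cells. Of 8 tested leukocyte markers, 2 rose and 1 fell under each siRNA, also when adjusted over the list alone (adjusted p = 0.725 and 0.932). The median under siRNA #2 was 0.29, the mean 0.14 and camera's direction down. Without control replicate 1, 4 rose and 1 fell under siRNA #1, and 2 rose and 1 fell under siRNA #2. CSF1R rose from 0.131 ± 0.0708 CPM to 0.485 ± 0.0587 and 0.610 ± 0.114 CPM. ITGAM rose 1.67-fold and 1.53-fold from 0.657 CPM, and its siRNA #2 call was lost in 7 of the 9 fits that left out a library, with an adjusted p of up to 0.13 without siRNA #2 replicate 3. Of 6 tested endothelial markers, 2 rose and 1 fell under siRNA #1, and 2 rose and 0 fell under siRNA #2, also when adjusted over the list alone (adjusted p = 0.79 and 0.204). ESAM rose 2.61-fold and 3.26-fold from 0.367 CPM. Of 16 pancreatic acinar and islet markers listed, 1 was tested and it was not called, also when adjusted over the list alone.

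**Figure D4:**
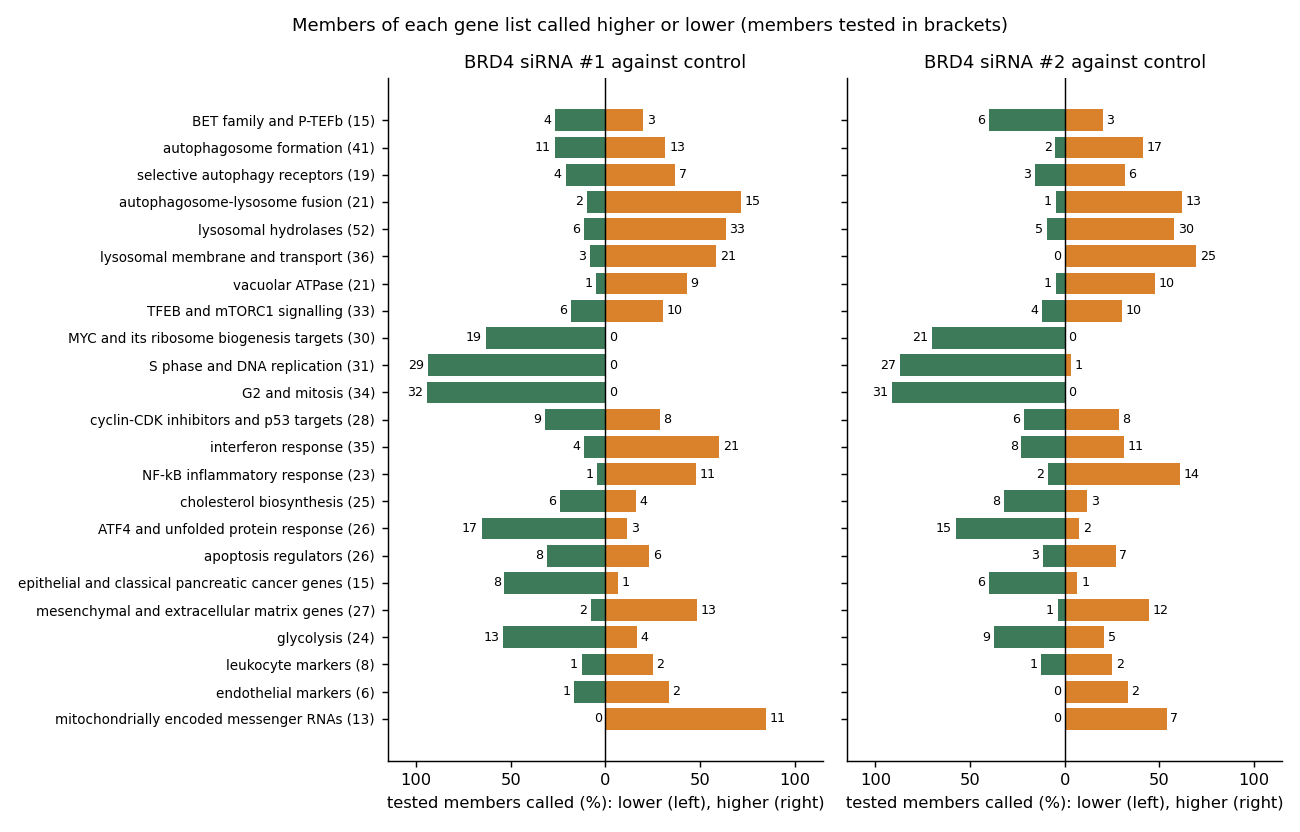
Percent of the tested members of each of 23 gene lists called higher (to the right) or lower (to the left) than control, for siRNA #1 and siRNA #2. In G2 and mitosis, 32 and 31 of 34 members were lower, and in lysosomal hydrolases 33 and 30 of 52 were higher.

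For the mean of both siRNAs against control, 36 hydrolases rose and 7 fell, 27 genes of the lysosomal membrane list rose and 1 fell, and 33 mitosis genes fell and 0 rose. With an estimated correlation, the lists that kept their calls for the mean were autophagosome-lysosome fusion (adjusted p = 0.0373), lysosomal membrane and transport (adjusted p = 0.0213), G2 and mitosis (adjusted p = 0.0373), and ATF4 and unfolded protein response (adjusted p = 0.0373).

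The 10 largest shared rises were in genes nearly silent in controls. SSPOP, annotated as a pseudogene, rose from 0.917 ± 0.266 CPM to 33.8 ± 3.20 and 17.3 ± 1.02 CPM. The long noncoding RNA ENSG00000273199 (chromosome 21, 37692090 to 37692968, minus strand) rose from 0.508 ± 0.252 CPM to 20.8 ± 3.17 and 23.8 ± 5.25 CPM. TBC1D10C, ITGAX, a leukocyte integrin, IFITM10, ANO3, LINC00854, the histone pseudogene H2BC16P, MIR3648 and ENSG00000187990, an ID without a match in the annotation, rose 8.11-fold to 52.3-fold. Some of these folds rest on very few control reads: TBC1D10C had 0, 1 and 5 counts in the control libraries, H2BC16P 5, 1 and 4, and ITGAX 3, 2 and 5. Without control replicate 3 the log2 values of TBC1D10C went from 5.41 and 5.44 to 7.17 and 7.20, and without control replicate 2 those of ANO3 went from 3.59 and 4.50 to 4.75 and 5.66. The IFITM10 exons share 22.2% of their bases with another gene on the same strand.

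The largest shared falls were in CHAC1 and BRD4, followed by ADM2, a peptide hormone, which fell 7.93-fold and 7.5-fold, and STC2, a secreted glycoprotein, which fell 8.35-fold and 4.45-fold. The glycine transporter SLC6A9 fell 6.10-fold and 4.70-fold, PLAC8 6.06-fold under each, and INPP5J 4.23-fold and 6.75-fold. The noncoding RNA DLEU2 fell 6.18-fold and 4.39-fold and its near-identical copy DLEU2L 5.39-fold and 4.91-fold, so their reads cannot be placed with certainty. ENSG00000270143, an ID without a match in the annotation, fell 5.08-fold and 5.13-fold.

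The siRNAs also differed from each other, which the comparison of siRNA #2 with siRNA #1 tested directly. It called 5052 genes, 2595 higher and 2457 lower under siRNA #2, and 618 and 677 of these differed at least 2-fold. CPD, a carboxypeptidase of the trans-Golgi, stood at 180 ± 48.7 CPM in controls and 244 ± 7.57 CPM under siRNA #1 but fell 8.14-fold to 22.1 ± 2.85 CPM under siRNA #2 (log2 difference -3.46, SE of each comparison 0.174 and 0.190, adjusted p = 2.0e-06). AMMECR1 fell 6.50-fold under siRNA #1, from 35.5 ± 7.26 to 5.47 ± 0.444 CPM, against 43.3 ± 1.72 CPM under siRNA #2 (log2 difference 2.98, adjusted p = 1.1e-06). PBX1, a homeodomain transcription factor, rose 7.81-fold under siRNA #1 and fell 2.12-fold under siRNA #2. ITGB8, an integrin that activates TGF-beta, rose 16.3-fold under siRNA #1 and had a log2 fold change of 0.40 under siRNA #2 (adjusted p = 0.12).

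OTOF and EPHA5 rose 3.47-fold and 4.15-fold under siRNA #1 and fell 3.13-fold and 1.96-fold under siRNA #2. MGLL, a monoacylglycerol lipase, fell 2.10-fold under siRNA #1 and rose 4.33-fold under siRNA #2, and CPA4, a carboxypeptidase, rose 13.4-fold under siRNA #2 from 0.253 CPM. A long noncoding RNA on chromosome 17 (38673144 to 38683254) stood 3.37 log2 higher under siRNA #2 than under siRNA #1, and another on chromosome 5 (38461027 to 38468441) 3.00 log2 higher. Some values against control turned on 1 library. CPD passed under siRNA #1 without control replicate 1 (adjusted p = 0.025), 2 or 3 (adjusted p = 0.036 each). CPA4 passed there without control replicate 3 (adjusted p = 0.042) or siRNA #2 replicate 2 (adjusted p = 0.047), and AMMECR1 passed under siRNA #2 without control replicate 2 (adjusted p = 0.046).

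Without control replicate 1, 8660 genes differed between the siRNAs, 5051 of them among the 5052, and with only the siRNA libraries in the fit 8570 differed. At least 2-fold, 682 were higher and 791 lower without control replicate 1. By list, G2 and mitosis gave adjusted p = 0.052 (11 lower and 2 higher under siRNA #2), or 0.671 with an estimated correlation. It passed at the preset correlation without control replicate 1 (adjusted p = 0.0127, with 17 lower and 4 higher), siRNA #1 replicate 2 (0.025), or siRNA #2 replicate 1 (0.0272) or 3 (0.0294). It also passed with library totals (0.0433), no filter (0.0143), a mean of 5 CPM (0.0379), only the groups compared (0.0202), limma-voom (0.0333) and fry (0.0172), and not with the block (0.0758). Glycolysis gave adjusted p = 0.0734, or 0.671 with an estimated correlation, and passed at the preset correlation without control replicate 1 (adjusted p = 0.0443), siRNA #2 replicate 1 (0.0359) or the filter (0.0143), and with fry (0.0102).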

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

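The tests of unequal knockdown, of a condition shared by experiment 1 and of both depth explanations were chosen after the result was seen, and the other tests of explanations and splits were set before.

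The siRNAs differed in 5052 genes although they left BRD4 at 18.1 and 14.8 CPM. Unequal knockdown as the whole cause would move nearly all shared genes further under 1 siRNA, but of 1216 genes called the same way whose difference passed its test, 45.9% moved further under siRNA #2 (41.3% to 50.3% when each library was left out in turn, a range added after the data were seen), and an earlier form of this test, the percent of genes called in opposite directions, gave 5.32% (310 of 5832), too near its bound of 5%, and was replaced once that was seen. A candidate explanation for part of the difference is each siRNA acting through its seed on other messages, since GACTTTG was the 3' UTR word most tied to lower levels under siRNA #1 (z = 15.92, permutation threshold 4.5) and AAGTCTA under siRNA #2 (z = 8.59, threshold 4.45), both at a permutation p of 0.001, the smallest that the permutations can give, and both words occur in BRD4 transcripts, as do 45.2% of all 7-base words. The word was carried by 25.7% of 1984 genes lower under siRNA #1 and 16.9% of 1692 lower under siRNA #2, against 14.6% and 7.5% of other genes. Most of these differing genes thus lacked that word in the 3' UTR. This cannot decide on seeds as the whole cause, since only the top word was counted. Further words passed the threshold, such as ACTTTGA (z = 9.36) for siRNA #1 and AGTCTAA (z = 8.33) for siRNA #2. A gene that changes downstream of a seed target also need carry no word. The siRNA sequences are not given in the sources used here, and of the genes furthest apart AMMECR1 and MGLL, lower under siRNA #1, and ITGB8, lower under siRNA #2, carried the word of that siRNA (MGLL both words), CPD and EPHA5, lower under siRNA #2, carried only the siRNA #1 word, PBX1, OTOF and CPA4 carried neither, and other off-target routes and effects of time or dose on each siRNA stay open and untested.

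Among all 12962 tested genes with an annotated 3' UTR, of any length or level, 9974 carried neither word. Genes that differed between the siRNAs were 30.6% of those with neither word and 38.2% of those with either. The words were picked for their tie to this difference and genes are not independent replicates, so these shares carry no p here.

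Control replicate 1 stood apart from control replicates 2 and 3, with an SD of log2 deviations over genes of 0.40 against 0.15. Lower depth was argued against by its total of 36427254 counts, above the lower of the other controls at 36078240. A bias with GC content or transcript length was argued against as the whole cause by an SD ratio that stayed at 2.1 after that trend was removed. The ratio was 2.7 before, so part of the deviation did go with GC content and length. A swap with a siRNA library was argued against by its BRD4 level, 5.28 times the highest siRNA library, and a condition of experiment 1 by correlations of -0.007 and -0.032 with the siRNA libraries of that number. It had the fewest genes detected of all libraries, 25178 against 27548 and 27474 in the other controls, and the highest share of counts in the top 10 genes (3.86%), and RNA quality, library complexity and a swap with a sample from outside stay open. No biological explanation was tested, since the design gives no groups within the controls, so a change in the state of that culture also stays open, with list medians such as 0.31 higher for MYC and its targets, 0.35 for the vacuolar ATPase and 0.37 for epithelial genes.

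Genes that were low in controls rose more often than they fell: of those under 1 CPM in controls, 1334 rose and 355 fell for the mean of both siRNAs, and of those under 1 CPM over all libraries, a split that does not favor rises, 929 rose and 533 fell. If genomic DNA or unspliced RNA lifted all low genes alike, few called low genes were predicted to be lower. Of the called genes that were low in controls, 21.0% were lower, with the median of these low genes 0.34 above that of the rest. The split over all libraries left 533 lower with a smaller gap (medians of 0.09 under 1 CPM and -0.04 at 10 CPM or more). Genes can fall beside such a lift, so these shares cannot decide on it. Higher depth was argued against by totals of at most 35365172 counts under the siRNAs against at least 36078240 in controls. Read-through from an expressed neighbor was predicted to lift low genes that the neighbor is transcribed toward above those it is transcribed away from. The reverse was seen, with medians of 0.38 (323 genes) and 0.77 (323 genes), a difference of -0.39 (permutation p = 0.0017). Read-through thus leaves the larger rise of the second class unexplained. It is not excluded for the first class, whose median also lay above that of low genes with no expressed neighbor. Low genes with no expressed neighbor within 10000 bases had a median of 0.07 (1349 genes), so low genes near an expressed one may be the part that rises with lower BRD4. This hypothesis was found on these data and was not tested. The strand of the low gene itself was not used in these classes. An effect of siRNA transfection on low genes other than through BRD4, and reads shared with neighbors on the other strand, stay open.

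Other splits of the libraries gave fewer genes than the real ones. For siRNA #1, siRNA #2 and the difference between them, 1 of 10 splits of 6 libraries gave as many genes, the real one, with 9090, 8318 and 5052 genes against 0 in the highest other split. These are too few splits for a share under 0.05. Of the 10, 4 parted every experiment number between the groups, and the highest other among them gave 0. For the mean of both siRNAs, 1 of 100 splits gave as many genes (9528, highest other 6452), and for genes changed the same way 1 of 100 (5522, highest other 3991), the real one in each. These shares are under 0.05. Most of the other splits mixed controls with siRNA libraries and gave 0 genes, so they are a weak standard and do not exclude chance. The highest other splits kept the 3 controls together and mixed the siRNA libraries. They still compared siRNA libraries with controls, so their high counts say nothing about chance or about the 3 groups.

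Several named genes differed between the siRNAs by edgeR's test of siRNA #2 minus siRNA #1 on the log2 scale. Among autophagy and lysosome genes the differences were 1.57 for WIPI1, 1.11 for PLEKHM1, 0.83 for CTSS, 0.55 for CTSV, 0.35 for TOLLIP, 0.35 for ATP6V0D1, 0.29 for SQSTM1, 0.29 for ATP6V1A and 0.25 for BECN1. They were -0.83 for SLC17A5, -0.43 for GNPTG, -0.41 for LAMP1, -0.34 for SIAE and -0.28 for ATP6AP1. With the experiment block the calls of GNPTG (adjusted p = 0.05), ATP6AP1 and ATP6V1A (0.057 each) were lost. Among cell cycle genes they were 1.15 for CDKN1A, 0.99 for E2F2, 0.84 for CDKN2C, 0.56 for PTTG1 and 0.50 for FEN1, and -1.20 for MAD2L1, -0.81 for CDKN1C and -0.45 for MCM3. Inflammatory and interferon genes gave 1.79 for CXCL5, -2.95 for OAS2, -1.68 for IFI44L, -0.81 for STAT1 and -0.39 for IFIT2. Genes of matrix, epithelium and metabolism gave 2.01 for MMP1, 0.53 for MMP14, 0.44 for VIM, -1.47 for CDH1, -0.54 for CLDN4, 0.56 for PFKFB4, -0.49 for HMGCR and -0.29 for MT-CYB. In the ATF4 list they were 0.48 for TRIB3, 0.48 for SESN2, -0.51 for PHGDH and -0.28 for PSAT1.

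Among the largest shared changes, the differences were 0.91 for ANO3, 0.64 for LINC00854, 0.91 for STC2, 0.49 for DLEU2, -1.51 for H2BC16P, -1.42 for ENSG00000187990, -0.96 for SSPOP and -1.87 for MIR3648. The genes furthest apart were MGLL at 3.19, AMMECR1 at 2.98 and CPA4 at 2.87, the long noncoding RNAs on chromosomes 17 and 5 at 3.37 and 3.00, and PBX1 at -4.05, ITGB8 at -3.63, CPD at -3.46, OTOF at -3.45 and EPHA5 at -3.02. By list, the siRNAs differed in autophagosome formation (adjusted p = 0.00836, or 0.0542 with limma-voom) and in the interferon response (adjusted p = 9.96e-11), and neither passed with an estimated correlation (adjusted p = 0.45 for each).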

How the results depend on the processing

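All alternatives for these counts and list tests were set before the data were examined, except the member counts and 2-fold counts without control replicate 1. No named gene or list that passed its test in either setting turned in direction. Whether more genes were higher or lower did turn, in 12 of 18 alternatives for siRNA #1, 2 of 18 for siRNA #2, 6 of 17 for the mean of both siRNAs, 1 of 18 for the difference between siRNAs and 2 of 18 for genes changed the same way. A mean of at least 5 CPM left fewer genes to test and gave 6014 for siRNA #1 and 6348 for the mean of both siRNAs. The test against a 1.2-fold change gave 6190 for the mean, 2777 for the difference between siRNAs and 3413 for genes changed the same way. With only the groups compared, 7780 genes changed under siRNA #1, 6709 under siRNA #2 and 4350 the same way, and 8570 differed between the siRNAs. That fit is not applicable to the mean of both. The main fit shares 1 spread per gene over groups whose median SD differed, at 0.221 in controls, 0.074 under siRNA #1 and 0.095 under siRNA #2. With an estimated correlation the adjusted p of the lists rose to 0.185 (autophagosome formation, siRNA #2), 0.125 (fusion, siRNA #1), 0.24 and 0.185 (hydrolases) and 0.0786 (lysosomal membrane, siRNA #1). The fry test gave 7.39e-04 and 1.29e-04 for the receptors and 0.0316 and 0.00224 for the vacuolar ATPase. For the vacuolar ATPase under siRNA #2, library totals gave 0.0396, no filter 3.94e-04, a mean of 5 CPM 0.0401, only the groups compared 0.0426 and limma-voom 0.0127, but an estimated correlation gave 0.396, the experiment block 0.0663 and median-of-ratios factors 0.0524. DESeq2 and glmTreat were not used for lists.

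Leaving out each library in turn, counts ranged from 7267 to 10629 for siRNA #1, 6602 to 10374 for siRNA #2, 8535 to 10810 for the mean, 3381 to 8660 for the difference (8660 without control replicate 1) and 4522 to 6785 for genes changed the same way. BRD4 ranged from -2.98 to -2.79 and from -3.27 to -3.07. The adjusted p of each list under siRNA #1 and siRNA #2 ranged over 0.557 to 0.919 and 0.00113 to 0.0158 for autophagosome formation, 7.26e-04 to 0.0128 and 2.22e-05 to 7.38e-04 for fusion, and 2.77e-13 to 1.60e-07 and 3.92e-14 to 3.21e-08 for hydrolases. It ranged over 8.69e-07 to 6.49e-04 and 1.30e-11 to 1.57e-07 for the membrane list, 0.175 to 0.494 and 0.0496 to 0.163 for receptors, and 0.0191 to 0.591 and 1.92e-04 to 0.105 for the vacuolar ATPase.

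With the experiment block, which pairs the libraries by number, 9154, 8397 and 9577 genes changed under siRNA #1, siRNA #2 and their mean, 5040 differed between the siRNAs, and 5583 changed the same way with 339 in opposite directions. Of the named genes against control, the block changed the call of MYC under siRNA #1 and for the mean (adjusted p = 0.015 against 0.092, and 0.018 against 0.11), and of the list tests it changed none. Between the siRNAs it ended the calls of GNPTG (0.05), ATP6AP1 and ATP6V1A (0.057 each) and added TFEB (0.043), HGSNAT (0.048) and INPP5J (0.047). The scalings moved the median of all genes by at most 0.045 on the log2 scale. Each of them gives levels relative to the rest of the library, so a change in RNA per cell was not measured. Named genes were not followed in the test against a 1.2-fold change, nor in fits whose filter left them out, so calls of small changes may depend on more than is listed here. Apart from the block and fits that left out a library, calls against control were lost under siRNA #1 for CDH1 (library totals, DESeq2, only the groups compared), WIPI1 (no filter, only the groups compared), PLEKHM1 (no filter), ATP6V0D1 and ATP6V1C2 (only the groups compared). Under siRNA #2 they were lost for ITGAM (DESeq2, no filter, only the groups compared) and ATP6V1C2 (these and limma-voom). CPD gained a call under siRNA #1 (DESeq2, limma-voom, a mean of 5 CPM). Over the named genes against control for each siRNA, and the genes furthest apart between the siRNAs, 63 values lost their call, 16 gained it and 4300 kept their side, the test against a 1.2-fold change left out. Over all list tests these numbers were 37, 61 and 1531.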

Other observations

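The classes of genes here were chosen after their values were seen, so they are descriptions of these libraries. More histone genes rose than fell under each siRNA, in a set that pools replication-dependent and variant histone genes. Of 34 tested, 23 rose and 3 fell under siRNA #1 (median log2 fold change 2.62), and 21 rose and 8 fell under siRNA #2 (median 1.06). H2AC6 rose from 25.5 ± 5.42 CPM to 239 ± 7.06 and 164 ± 5.14 CPM, and H2AC11 from 9.76 ± 0.795 CPM to 143 ± 4.16 and 50.4 ± 3.62 CPM. The linker histone H1-2 rose from 56.0 ± 12.4 CPM to 319 ± 13.7 and 106 ± 9.27 CPM. Other members moved down, H2AZ1 from 491 ± 133 CPM to 240 ± 5.37 and 215 ± 11.9 CPM and H1-0 from 83.5 ± 6.18 CPM to 55.8 ± 3.44 and 57.9 ± 3.96 CPM (SD, n = 3), and H2AZ2 by 0.28 and 0.24 on the log2 scale. H2AX, H1-10, H3-3A, H2BC13 and H2AC20 were called lower under siRNA #2 and not called under siRNA #1 (siRNA #2 log2 fold changes of -0.43, -0.52, -0.72, -1.09 and -1.07). The variant H2AJ rose (0.81 and 0.61, adjusted p = 0.0015 and 0.0077). Under library totals the counts were 23 and 3, and 21 and 7, under median-of-ratios factors 23 and 3, and 21 and 8, and without control replicate 1 they were 27 and 3, and 20 and 7. Many histone genes have near-identical copies, so reads of single genes are uncertain. Whether counts from this library kit follow the total level of histone messages was not tested.

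More long noncoding RNAs rose than fell for the mean of both siRNAs, with 812 of 2028 tested higher and 199 lower (median 0.42). More processed pseudogenes, copies of other genes' messages, fell than rose, with 856 of 2657 lower and 134 higher (median -0.30), and their reads can come from the parent gene. Of 13022 protein-coding genes, 3476 were higher and 3548 lower, or 3761 and 3216 with library totals, a balance that depends on the scaling. The medians of long noncoding RNAs and processed pseudogenes were 0.46 and -0.26 with library totals, 0.43 and -0.30 with median-of-ratios factors, and 0.44 and -0.20 without control replicate 1.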
